A study of Caenorhabditis elegans with 78 samples.

How the data were processed

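The series holds 78 chromatin immunoprecipitation sequencing (ChIP-seq) samples of Caenorhabditis elegans first-stage (L1) larvae, of which 20 are inputs. Peak lists of 32 libraries were used, 16 for histone H3 trimethylated at lysine 4 (H3K4me3, a mark of active promoters) and 16 for histone H3 dimethylated at lysine 9 (H3K9me2, a mark of repressed chromatin). Each mark had 2 libraries for each of 4 genotypes at each of 2 temperatures, 20 and 26 °C. The genotypes were wild type and the mutants lin-15B(n744), lin-35(n745) and lin-37(n758). The samples for H3K27me3 (8), H3K36me3 (18) and input (20) were not analysed here. Per the labels' protocols, worms for 26 °C were moved from 20 °C as fourth-stage larvae, and the L1 progeny hatched without food were frozen. Both H3K4me3 and H3K9me2 were immunoprecipitated from crosslinked, sonicated extract. Per the labels, H3K9me2 was processed by hand and H3K4me3 on an automated instrument. Groups and replicate numbers were taken from the labels. Nothing in the labels said that replicates were separate cultures, so p-values of per-library values measure the spread between these libraries, which may be technical. P-values of Fisher's exact tests and of matched draws treat regions or sites as separate units and measure no spread between libraries.

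Reads were aligned with Bowtie 1.1.2 to genome build ce10 and peaks were called with MACS2, per the submitters' processing notes; a MACS2 version was not given in the sources used here. Each library had its own peak list, called against an input library, per the labels. Peak names in the deposited lists gave a q cutoff of 0.01 in 31 libraries and of 0.05 in 1 (H3K9me2, lin-15B, 20 °C, replicate 1). They also gave an extension size of 250 bp for H3K4me3 and a shift size of 125 bp for H3K9me2. The deposited H3K4me3 lists are narrow peaks with a fold enrichment at the summit and the −log10 p and −log10 q of that summit, as the authors' caller wrote them. The deposited H3K9me2 lists are broad peaks with 3 score columns. Which of fold, p and q each of these score columns holds could not be settled from the values, so the score was used only to rank peaks within 1 list. The lists carry no read counts. The sequencing depth behind each peak is therefore unknown, and a missing peak says that no peak was called, not that the mark was absent.

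Sub-peaks of H3K4me3 that repeated the start and end of a region were collapsed to 1 peak. The number of peaks, the covered length, the share of autosomal covered length on chromosome arms and the share of covered length on X were computed per library. Arms were the outer 30% at each end of an autosome and centres the rest, with the highest peak end taken as the chromosome length. Peaks of the 16 libraries of a mark were merged into regions, and a region was called in a library when a peak overlapped it by at least 1 bp. A region was lost in a mutant when it was called in all 4 wild-type libraries and in none of the 4 mutant libraries, over both temperatures. Gained regions were the reverse. The number of lost and gained regions was set against all 35 splits of the same 8 libraries into 4 and 4, which allow a share no smaller than 0.0286. For temperature, a region had to be called in at least 7 of 8 libraries at 1 temperature and at most 1 of 8 at the other, and 100 splits within genotype were drawn.

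Per-library values were compared over the 4 genotypes by a permutation test with 100000 draws within temperature, for which 1e-05 is the smallest p, and between a mutant and wild type by an exact permutation test of the difference of means. With 4 libraries against 4 the smallest exact two-sided p is 0.0286. Temperature labels were permuted exactly within genotype, in 1296 arrangements. Counts were compared by Fisher's exact test. All tests were two-sided. Benjamini-Hochberg adjustment covered 12 tests over genotypes, 36 mutant against wild-type tests, 9 temperature tests, 36 tests of chromosome zones, 3 tests of each relation between the marks, 9 of those relations within zones and 9 matched comparisons. Lost H3K9me2 regions were also compared with 10000 draws of wild-type regions matched on covered length and score rank. For overlaps between mutants, which share the wild-type libraries, 100 unchanged data sets were simulated, and the overlap expected of independent lists was computed, also with the wild-type libraries divided between the mutants.

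The plan, fixed before the data were examined, called for promoters of annotated genes and for germline and somatic gene lists. A gene annotation in the build of the files was not used here, so no peak was assigned to a gene, the promoter and list results were not run, and the planned substitute of merged regions was used. Merged H3K4me3 regions stood in for promoters in the comparison of the 2 marks. That substitution, the comparisons of zones, X shares and matched regions, the 1 kb bins, the 200 bp overlap for lost and gained regions, the temperature counts, the splits balanced for temperature and the comparisons within library sets of either mark were chosen after seeing the data. The planned rule for named genes could not be applied. In its place the first 10 regions of each list were considered, ordered by mean fold enrichment for H3K4me3 and by mean rank percentile of the score within each list for H3K9me2; any other region is named with its reason. Alternatives were a −log10 q of at least 2 (which removed 0 peaks) or 5 for H3K4me3, equal peak numbers (7420 for H3K9me2 and 5421 for H3K4me3), at least 3 of 4 against at most 1 of 4 libraries, arms of 25%, a replicate block, and leaving out each library in turn.

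Library codes in the names of the deposited lists divided the H3K4me3 libraries into 1 set of 8, with 1 library per genotype and temperature, and 8 others. The 8 others carried more than 1 code, so comparisons among them are not within 1 set. Among them, lin-37 26 °C replicate 2 shared its code with no other library. Of the H3K9me2 sets, 2 held 1 wild-type library together with lin-15B and lin-35 libraries, and site and X shares were compared within them. No lin-37 library shared a set with wild type, so set and genotype cannot be told apart for H3K9me2 in lin-37. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The code for the region counts was checked on simulated data. Planted regions were set to meet the rule for a switched region, so their recovery was fixed by construction. It says nothing about switches missed through missing peak calls. With 400 switched regions planted, 400 of 400 were recovered in the simulated H3K9me2 comparison of 16691 regions, with 25 other calls. All 400 were recovered in the simulated H3K4me3 comparison of 10328 regions, with 17 other calls.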

Results

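The 32 peak lists covered H3K9me2 and H3K4me3 in L1 larvae of 4 genotypes at 20 and 26 °C, with 4 libraries per genotype and mark. All 3 mutated genes belong to the synMuv B class of chromatin regulators. LIN-35 is the worm's retinoblastoma-like protein, LIN-37 is a subunit of the DREAM repressor complex, and LIN-15B is a THAP-domain protein. The series asks which chromatin changes accompany the altered gene expression of these mutants, and its title concerns H3K9me2 on germline gene promoters. H3K9me2 lists held 7420 to 13766 peaks and H3K4me3 lists 5421 to 8412. Libraries of the same genotype and temperature had a mean Jaccard index (overlap divided by union of covered length) of 0.636 for H3K9me2 (0.457 to 0.725 over 8 pairs) and 0.662 for H3K4me3 (0.485 to 0.763), lowest in lin-15B at 20 °C for both. Pairs of other genotypes at the same temperature had means of 0.580 and 0.637, and no list was a duplicate of another.

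H3K9me2 lay mainly on chromosome arms in all 4 genotypes. In wild type 94.1% ± 1.05 (SD, n = 4) of the autosomal H3K9me2 length lay on chromosome arms, and the mutants had 95% ± 2.06 (lin-15B), 94.0% ± 0.847 (lin-35) and 94.1% ± 0.612 (lin-37). The wild-type lists held 9020 ± 750 peaks, against 10690.5 ± 2312 in lin-15B, 8732 ± 1545 in lin-35 and 9117 ± 1287 in lin-37. H3K4me3 peak numbers were 6258.5 ± 836 in wild type and 6957 ± 1464, 6228 ± 787 and 6359 ± 755 in the mutants in the same order. No difference between genotypes passed the permutation test for these values (adjusted p = 0.481 for H3K9me2 peak number, 0.753 for its arm share and 0.753 for H3K4me3 peak number). Of H3K4me3 length 49.3% ± 0.741 lay on arms in wild type and 50.7% ± 0.630 in lin-37, where all 4 libraries exceeded wild type, but the exact permutation p of 0.0286 became 0.0857 after adjustment over 36 tests, and the permutation test over genotypes gave an adjusted p of 0.197. The exact p was 0.0571 without any 1 of the 4 wild-type libraries or of the lin-37 26 °C replicates 1 and 2. Without lin-15B 20 °C replicate 2 the H3K4me3 arm share differed over genotypes at an unadjusted permutation p of 0.0354, and without lin-15B 20 °C replicate 1 so did H3K9me2 peak number (0.0351).

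Each mutant lost H3K9me2 from a set of discrete regions. Of 5135 regions called in all 4 wild-type libraries, 279 were lost in lin-15B (5.43%), 192 in lin-35 (3.74%) and 147 in lin-37 (2.86%). Gained regions numbered 186 in lin-15B, 32 in lin-35 and 17 in lin-37 out of 7134 called in no wild-type library. Lost and gained regions together numbered 465, 224 and 164, and the real grouping gave the highest count of the 35 splits in each mutant, the highest other splits giving 104, 55 and 67. Within 20 °C alone, with 2 libraries against 2, 763, 416 and 534 regions were lost in lin-15B, lin-35 and lin-37, and within 26 °C 596, 802 and 463. Gains within 20 °C were 741, 455 and 891, and within 26 °C 1112, 206 and 128, so that they outnumbered losses in lin-35 and lin-37 at 20 °C and in lin-15B at 26 °C. Leaving out wild type 26 °C replicate 2, the list with the shortest covered length in wild type (7.54 Mb), raised the losses to 471 in lin-15B and 283 in lin-37. The library of lin-15B 20 °C replicate 1 had the looser q cutoff, yet the fewest peaks (8273) and shortest covered length (7.97 Mb) of the lin-15B lists. Without it lin-15B gained 679 regions and lost 292. With at least 3 of 4 against at most 1 of 4 libraries lin-15B gained 1313 and lost 873. Its gains were 76 with equal peak numbers.

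**Figure D1:**
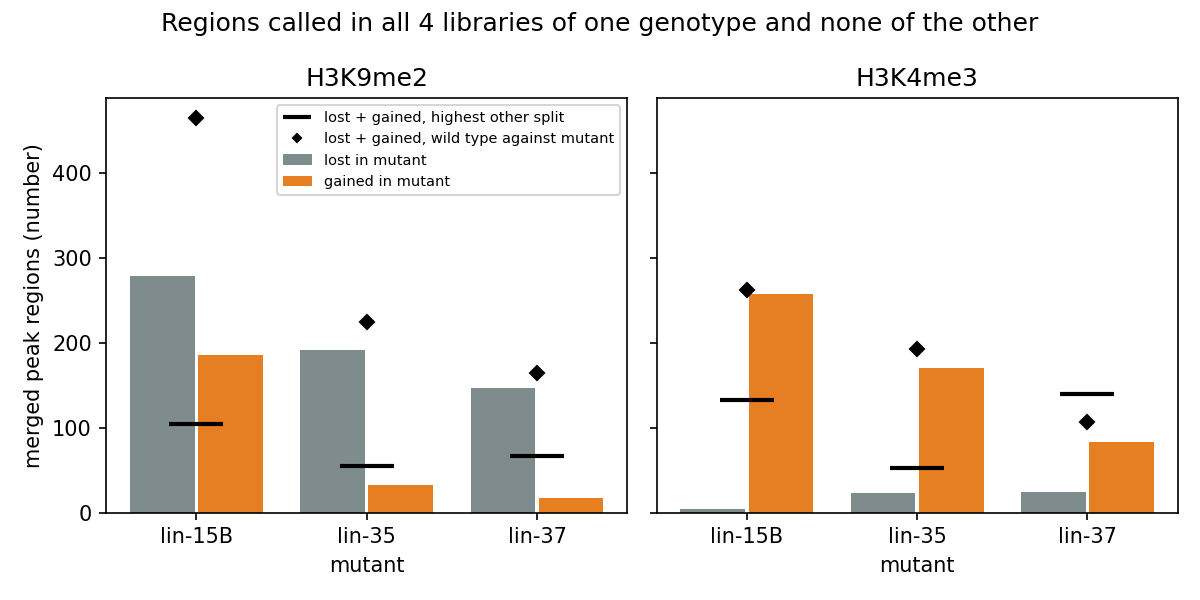
Number of merged peak regions called in all 4 libraries of one genotype and in none of the other, for each mutant against wild type. Bars give lost and gained regions, diamonds their sum and horizontal marks the highest sum in any other split of the same 8 libraries; the sum of 107 for H3K4me3 in lin-37 is the only one below its mark, at 140.

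Counts of gained H3K9me2 regions in lin-35 and lin-37 also moved with single libraries. In lin-35 the count of 32 became 57 without wild type 20 °C replicate 2 and 61 without lin-35 26 °C replicate 2. In lin-37 the count of 17 became 42, 30 and 31 without wild type 20 °C replicate 2, 26 °C replicate 1 and 26 °C replicate 2. It became 29, 62 and 26 without lin-37 20 °C replicate 2, 26 °C replicate 1 and 26 °C replicate 2.

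The lost H3K9me2 regions lay more often in chromosome centres than the regions that were not lost. Centres held 39.1% of the regions lost in lin-15B against 11.3% of the other wild-type regions, an odds ratio of 5.01 (Fisher's exact test, adjusted p = 9.1e-29). The odds ratio by the same exact test was 3.84 for lin-35 (34.4% against 12.0%, adjusted p = 3.4e-14) and 4.75 for lin-37 (39.5% against 12.1%, adjusted p = 2.6e-15). The lost regions were short, with a median wild-type covered length of 418, 414 and 394.5 bp against 825 bp for all 5135. Against draws matched on covered length and score rank, the centre shares remained higher (matched means 21%, 20.2% and 20.4%, permutation p = 2.0e-04 each, the smallest that 10000 draws can give). With at least 3 of 4 against at most 1 of 4 libraries the centre odds ratios were 2.12 for lin-35 and 2.33 for lin-37. Regions that gained H3K9me2 in lin-15B had the opposite placement, with 1 of 186 in a centre against 17.8% of the other regions (odds ratio 0.0249, Fisher's exact test, adjusted p = 1.1e-13). Each gained region had to be called in lin-15B 20 °C replicate 1, whose arm share of 97.4% was the highest of the H3K9me2 lists. Whether the placement rests on that library was not tested. X held 31.2% of them against 26.6% of the other regions, which did not pass (Fisher's exact test, adjusted p = 0.307).

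Many of the lost regions with the highest-ranked wild-type H3K9me2 peaks also overlapped an H3K4me3 peak. The marks were called in separate libraries of larvae and joined by overlap. Both marks at a region or site therefore need not lie in the same cells or on the same stretch. In ce10 coordinates, X 15724853 to 15726043 (rank percentile 97.7 ± 2.59, n = 4) was called for H3K9me2 in 4 of 4 wild-type, lin-35 and lin-37 libraries and in 0 of 4 lin-15B libraries, with an H3K4me3 peak in all 16 libraries. II 13574994 to 13576745 (97.5 ± 1.38) was lost in both lin-15B and lin-35, and V 10813172 to 10813857 (94.6 ± 0.346) likewise, with 2 of 4 lin-37 libraries still called at each. I 4384758 to 4386316 (91.9 ± 6.38), on the left arm, was lost in lin-15B alone; its H3K4me3 was called in no wild-type library and in all 12 mutant libraries. IV 7575067 to 7575735 (95 ± 1.91) was lost in lin-35 and called in all 4 libraries of each other genotype. In lin-37 the first 5 regions by rank, from V 2355213 to 2543484, lay in a single segment of the left arm of V and had no H3K4me3 peak in any library.

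The same regions were lost in several mutants. Of the lost H3K9me2 regions 95 were shared by lin-15B and lin-35, 112 by lin-15B and lin-37, 81 by lin-35 and lin-37, and 69 by all 3. Independent lists would share 10.4, 7.99 and 5.50, and simulated unchanged mutants set against the same wild-type libraries shared 1.7, 1.89 and 1.65 on average (at most 6, 6 and 9). With nothing planted in the simulated check, at most 36 H3K9me2 regions switched. Lists of unchanged mutants are thus short, and their overlap is no reference for longer lists. Independence takes every region as equally likely to be lost, although the lost regions were short. With the wild-type libraries divided between the 2 mutants, the shared count is the same by construction and at most 12.0, 9.78 and 8.02 were expected. Without wild type 26 °C replicate 2 the shared losses were 172, 215 and 154.

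H3K4me3 was gained in more regions than it was lost when all 4 libraries against none were asked for. Out of 3195 regions with no wild-type peak, 258 gained H3K4me3 in lin-15B, 170 in lin-35 and 83 in lin-37, while 4, 23 and 24 of 4299 were lost. With at least 3 of 4 against at most 1 of 4 libraries, gains and losses lay closer together in lin-35 (338 and 261) and lin-37 (251 and 188), and were 629 and 96 in lin-15B. Gains overlapped between the mutants, with 107 regions for lin-15B and lin-35, 69 for lin-15B and lin-37, 66 for lin-35 and lin-37, and 60 in all 3. Independent lists would share 13.7, 6.70 and 4.42. With divided wild-type libraries the shared counts are the same by construction, and independent lists would then share at most 6.62, 4.32 and 2.88. Independence takes every region as equally likely to be gained, which was not tested. Simulated unchanged mutants shared 0.62, 0.64 and 0.54 on average, from short lists that are no reference for longer ones. The sum of lost and gained regions (262, 193 and 107) was the highest of 35 splits in lin-15B and lin-35, with 132 and 53 in the highest other split. In lin-37 the split of the same libraries by temperature gave 140, so 2 of 35 splits were as large; with 2 libraries of each temperature on each side (18 splits), the highest other gave 12. Within temperature, gains in lin-15B, lin-35 and lin-37 were 453, 366 and 238 at 20 °C and 530, 321 and 380 at 26 °C. Losses were 12, 88 and 217 at 20 °C and 185, 355 and 141 at 26 °C, more than the gains for lin-35 at 26 °C. For lin-15B the sum of 465 at 20 °C was below that of the split by library set (486), and at 26 °C 715 stood against 663 in the split by set.

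The highest other H3K4me3 split in lin-15B followed the library set. Within the set of 8 libraries 929, 285 and 114 regions were gained in lin-15B, lin-35 and lin-37, and among the other libraries 319, 254 and 353. Losses were 29, 120 and 226 within the set, more than the gains for lin-37, and 316, 178 and 90 among the others. With 2 libraries against 2, the real sums within the set were 958, 405 and 340 and the highest other splits gave 308, 347 and 597, the last above the real sum of lin-37. Without lin-15B 20 °C replicate 1 the gains in lin-15B were 426. The small numbers of lost regions moved more. For lin-15B the 4 became 7 and 8 without wild type 20 °C replicates 1 and 2, and 34 and 8 without lin-15B 20 °C replicate 2 and 26 °C replicate 2. For lin-35 the 23 became 49, 40 and 35 without wild type 20 °C replicate 1, 20 °C replicate 2 and 26 °C replicate 2, and 64 and 41 without lin-35 20 °C replicate 1 and 26 °C replicate 2. For lin-37 the 24 became 47 without wild type 26 °C replicate 2 and 54 without lin-37 26 °C replicate 1.

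H3K4me3 gains were concentrated on chromosome arms, in a comparison not matched on width or on the number of libraries that called a region. Arms held 74.0% of the regions gained in lin-15B against 50.3% of the other regions without wild-type H3K4me3 (odds ratio 2.81, Fisher's exact test, adjusted p = 4.9e-13). By the same exact test the shares were 61.8% against 51.7% in lin-35 (odds ratio 1.51, adjusted p = 0.0290) and 69.9% against 51.8% in lin-37 (odds ratio 2.16, adjusted p = 0.00318). For lin-35 the odds ratio was 1.26 with equal peak numbers and no longer passed (Fisher's exact p = 0.155), and for lin-15B it was 5.14 in 1 kb bins. X held 3.10% of the gains in lin-15B against 16.8% of the other regions (odds ratio 0.159, Fisher's exact test, adjusted p = 1.1e-10), and 8.82% against 16% in lin-35 (odds ratio 0.507, adjusted p = 0.0290). For lin-37 the X shares were 8.43% and 15.8% and did not pass (Fisher's exact test, adjusted p = 0.142).

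H3K4me3 appeared in the mutants more often at sites that carried H3K9me2 in wild type than at other sites. Gaining sites and the rest were not matched on width or on the number of libraries that called them. Of the 258 sites that gained H3K4me3 in lin-15B, 166 (64.3%) had H3K9me2 in all 4 wild-type libraries, against 542 of 2937 other sites without wild-type H3K4me3 (18.5%), an odds ratio of 7.97 (Fisher's exact test, adjusted p = 2.2e-52). By the same exact test the shares were 59.4% of 170 sites in lin-35 (odds ratio 5.83, adjusted p = 4.2e-27) and 69.9% of 83 in lin-37 (odds ratio 8.79, adjusted p = 6.0e-21). On the arms alone the odds ratios were 5.06, 4.14 and 5.77, in the centres 17.3, 13.1 and 19.1, and on X 23.6, 33.5 and 31.5, each with an adjusted Fisher's exact p of at most 2.5e-04. On X they rest on 4 of 8, 8 of 15 and 4 of 7 gained sites. The shares of gained sites were 70.7%, 68.6% and 75.9% on arms and lower in centres (45.8%, 42% and 55.6%). The higher odds ratios reflect few other sites with H3K9me2, at most 6.15% in centres and 4.07% on X against at least 32.3% on arms. Within the set of 8 libraries the shares with wild-type H3K9me2 were 33.2%, 49.1% and 59.6% of the gained sites in lin-15B, lin-35 and lin-37 (odds ratios 2.41, 4.13 and 5.86). Among the other libraries they were 58.6%, 50% and 32.3% (odds ratios 6.41, 4.21 and 1.92). The odds ratios were 5.03, 3.65 and 4.76 with equal peak numbers, with at least 3 of 4 against at most 1 of 4 libraries 4.78 in lin-15B and 3.29 in lin-37, and in 1 kb bins 16.7 in lin-37.

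Sites that gained H3K4me3 also lost H3K9me2 more often than other sites with wild-type H3K9me2. The comparison took the 708 sites with H3K9me2 in all 4 wild-type libraries and no wild-type H3K4me3. Those that did not gain it include sites called in only some libraries of the mutant, and width was not matched. How far this adds to the difference was not tested. In lin-15B 51 of the 166 sites that gained H3K4me3 lost H3K9me2 (30.7%), against 35 of 542 that did not (6.46%), an odds ratio of 6.42 (Fisher's exact test, adjusted p = 4.5e-14). By the same exact test it was 20 sites in lin-35 (19.8%) against 2.47%, an odds ratio of 9.74 (adjusted p = 1.1e-09), and 16 of 58 in lin-37 (27.6%) against 2.77%, an odds ratio of 13.4 (adjusted p = 5.6e-10). Within the set of 8 H3K4me3 libraries these odds ratios were 7.02, 10.9 and 12.7, and among the others 9.45, 14.5 and 11.3. The odds ratio for lin-37 was 6.94 without wild type 26 °C replicate 2 and, with at least 3 of 4 against at most 1 of 4 libraries, 5.07 (4.95 for lin-35). In 1 kb bins the odds ratio for lin-15B was 2.46, and with an overlap of 200 bp that for lin-35 was 14.9.

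Several of these sites switched both marks in all 3 mutants. At IV 13450139 to 13451622 (ce10, 1484 bp, right arm) H3K9me2 was called in 4 of 4 wild-type libraries and 0 of 12 mutant libraries, and H3K4me3 in 0 of 4 and 12 of 12. The authors' fold enrichment of its H3K4me3 peaks was 20.6 ± 4.73 in lin-15B, 24.6 ± 9.73 in lin-35 and 25.8 ± 10.8 in lin-37 (mean ± SD, n = 4). The same switch of both marks was seen at III 5155494 to 5157222 (fold 19.6 ± 4.18, 22.1 ± 9.49 and 24.8 ± 11.6), X 8147351 to 8148095, V 11554123 to 11555141 and II 6893395 to 6894664. Other sites switched H3K9me2 in 1 mutant only. IV 193813 to 195031, with the highest fold among the 51 lin-15B sites that switched both marks (36.2 ± 12.9), lost H3K9me2 in lin-15B while 2 of 4 lin-35 and 4 of 4 lin-37 libraries kept it. III 12362857 to 12363856 had H3K4me3 in 4 of 4 lin-35 libraries with H3K9me2 still called in all 4.

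**Figure D2:**
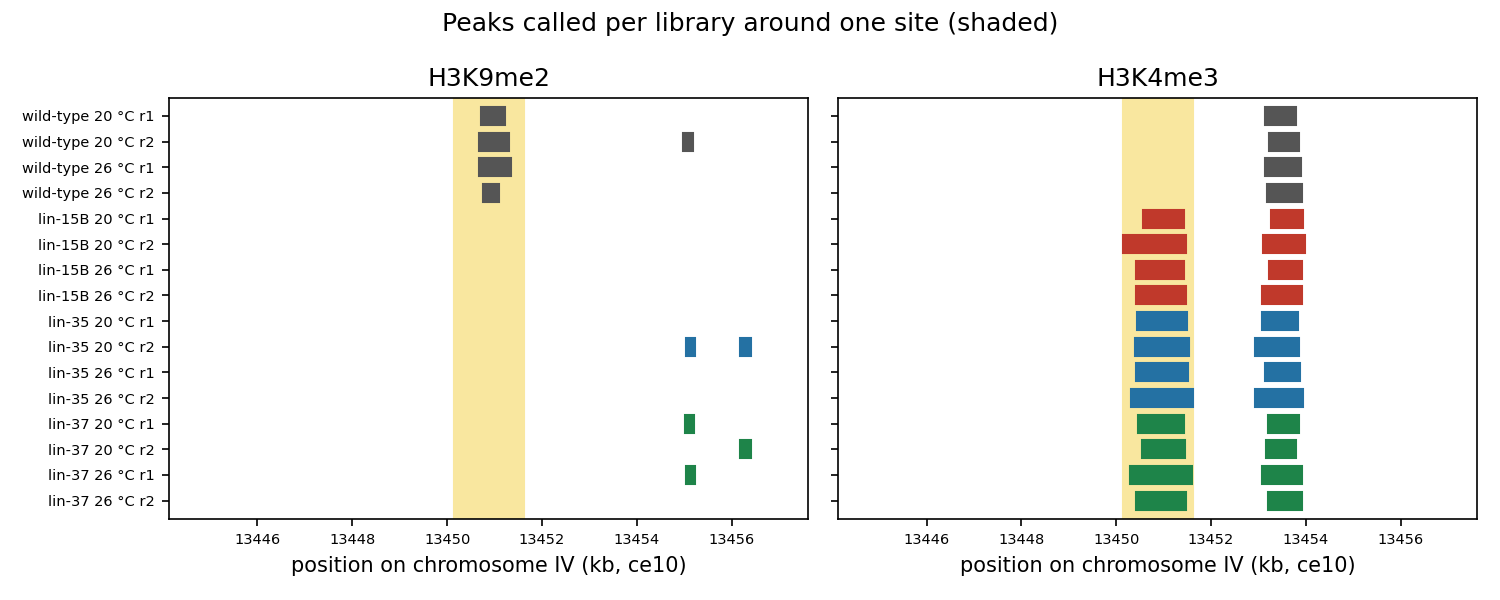
Peaks of each library around IV 13450139 to 13451622 (shaded), with 1 line per library, the position in kb of ce10 on the horizontal axis and colours for genotypes. In the shaded site the 4 wild-type libraries have H3K9me2 and no H3K4me3, and the 12 mutant libraries have H3K4me3 and no H3K9me2; the neighbouring H3K4me3 peak is present in all 16.

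The share of gained sites with an H3K9me2 peak, counted in every library, separated wild type from the mutants. At the 258 sites of lin-15B, H3K9me2 was called at 79.3% ± 7.91 in wild type (n = 4), 36.9% ± 6.49 in lin-15B, 61.4% ± 1.72 in lin-35 and 56.8% ± 5.30 in lin-37. At the 170 sites of lin-35 the shares were 75.4% ± 8.13, 32.2% ± 6.52, 42.8% ± 4.33 and 46.9% ± 5.73, and at the 83 sites of lin-37 83.4% ± 7.25, 30.4% ± 7.58, 47.3% ± 3.60 and 38.3% ± 6.17. All 3 classes of sites differed over the genotypes (permutation test, adjusted p = 1.6e-04 each), and every mutant library lay below every wild-type library. Single mutants against wild type gave the smallest exact permutation p the design allows, 0.0286, and 0.0857 after adjustment over 36 tests. Within the H3K9me2 library sets that held wild type, with 1 wild-type library each, the share at the mutant's own sites was 76.0% in wild type and 31% and 34.5% in lin-15B in the first set, and 69.8% and 46.1% in the second. For lin-35 it was 74.1% in wild type and 45.9% and 40% in lin-35 in the first set, and 64.7% and 38.2% in the second; lin-37 shared no set with wild type. The wild-type library was at 20 °C in the first set and at 26 °C in the second, so 2 of 3 lin-15B comparisons and 1 of 3 for lin-35 were across temperatures, and 1 library of each of these mutants shared no set with wild type. At 3429 sites with H3K4me3 in all 16 libraries the shares were 27.4% ± 3.39 in wild type and 21.6% ± 5.42, 23.3% ± 2.33 and 21.8% ± 2.13 in the mutants (permutation test, adjusted p = 0.333).

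**Figure D3:**
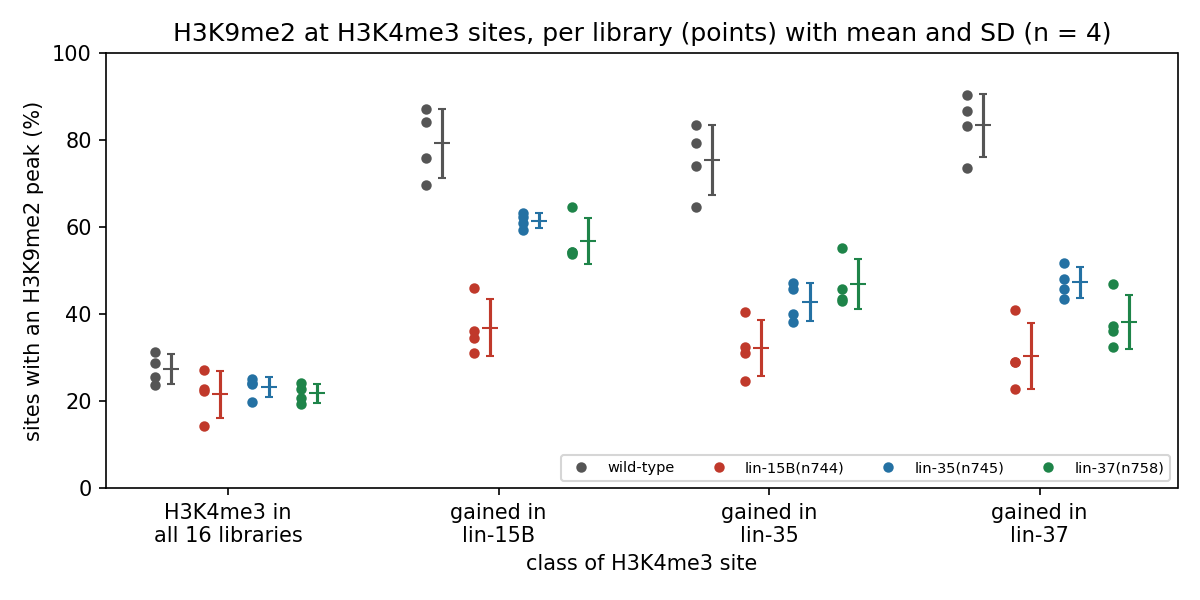
Percentage of H3K4me3 sites that overlap an H3K9me2 peak, for sites with H3K4me3 in all 16 libraries and sites that gained it in each mutant. Points are libraries, horizontal marks means and bars SD (n = 4); at each gained class every mutant library lies below every wild-type library, for example 31 to 46.1% in lin-15B against 69.8 to 87.2% in wild type.

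Seen from H3K9me2, a minority of the lost regions had H3K4me3 switched on, more than in matched draws. H3K4me3 was switched on, from no wild-type library to all 4 mutant libraries, in 17.2% of the regions lost in lin-15B, 11.5% in lin-35 and 10.9% in lin-37, against 2.90%, 2.24% and 1.28% of matched draws (permutation p = 2.0e-04 each). A further 28.3%, 25.0% and 25.2% already had H3K4me3 in all 4 wild-type libraries, against 11.2%, 11.1% and 9.96% of matched draws (permutation p = 2.0e-04 each). Any library had H3K4me3 in 73.5%, 60.9% and 64.6% of the lost regions, against 38.0%, 39.7% and 38.1% of regions kept in all 4 mutant libraries. All 4 mutant libraries had it in 55.2%, 50% and 50.3% of the lost and 16.8%, 17.6% and 16.1% of the kept regions. The kept regions were not matched on length.

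X carried little H3K9me2 in wild type, and more in some mutant libraries. The X share of covered length was 4.57% ± 0.631 in wild type, 9.88% ± 3.72 in lin-15B, 6.23% ± 0.630 in lin-35 and 5.89% ± 0.155 in lin-37 (n = 4). All 4 libraries of lin-35 and of lin-37 lay above every wild-type library, as did 3 of 4 of lin-15B. The permutation test over genotypes gave p = 0.0200 and an adjusted p of 0.0601 over 12 tests, so the difference failed the correction. With 1 library left out, the unadjusted permutation p ranged from 5.0e-05 (without lin-15B 20 °C replicate 1) to 0.0382 (without lin-15B 20 °C replicate 2). Exact permutation p against wild type was 0.0857, 0.0286 and 0.0286 (adjusted 0.206, 0.0857 and 0.0857). Without lin-15B 20 °C replicate 1 it was 0.0286 for lin-15B (difference 6.97 points, and 5.31 with it), and without wild type 20 °C replicate 1 it was 0.0571 for lin-35. Within the first of the sets with wild type the X shares were 3.74% in wild type, 4.88% and 13.8% in lin-15B and 5.54% and 6.51% in lin-35, and within the second 5.08%, 9.89% and 5.90% in the same order, with the same comparisons across temperatures. H3K4me3 X shares were 14.2% ± 0.828, 12.8% ± 1.90, 12.9% ± 1.64 and 13.6% ± 1.11 (permutation test, adjusted p = 0.481).

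**Figure D4:**
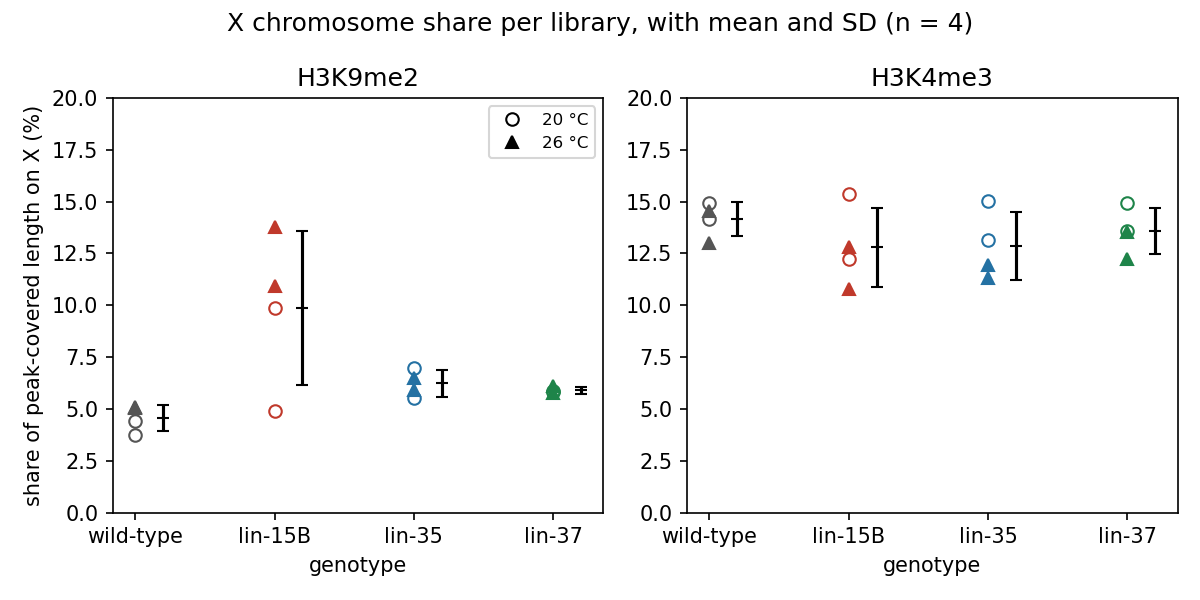
Share of peak-covered length on X in each library, in percent, by genotype, with open circles for 20 °C, triangles for 26 °C and bars for mean and SD (n = 4). For H3K9me2 the lin-15B libraries range from 4.88 to 13.8% and the wild-type libraries from 3.74 to 5.08%; for H3K4me3 the genotypes overlap.

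Temperature moved few regions in the same way in all genotypes. With at least 7 of 8 libraries at 1 temperature and at most 1 of 8 at the other, 61 H3K4me3 regions were called at 26 °C only and 2 at 20 °C only. For H3K9me2 the direction was the other way, with 38 regions at 20 °C only and 5 at 26 °C only. The sums of 63 and 43 were each the highest of 100 splits within genotype, the highest others being 25 and 27. Within a genotype, with 2 libraries against 2, H3K4me3 regions called at 26 °C only outnumbered those at 20 °C only in all 4 (409 against 17 in wild type, 115 against 37 in lin-15B, 215 against 161 in lin-35 and 707 against 92 in lin-37). For H3K9me2, regions called at 20 °C only numbered 238 in wild type and 301 in lin-15B, against 329 and 411 at 26 °C only, and 643 in lin-35 and 924 in lin-37, against 77 and 181.

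With all peaks, per-library values gave no temperature difference that passed correction over 9 tests. The H3K4me3 X share was 14.2% ± 1.1 at 20 °C and 12.5% ± 1.21 at 26 °C (n = 8, exact permutation p = 0.0139, adjusted 0.125). The H3K9me2 X share was 5.89% ± 1.89 and 7.39% ± 3.20 (exact permutation p = 0.0509, adjusted 0.229); the unadjusted p was 0.0494, 0.00926, 0.0293 and 0.0432 without lin-15B 20 °C replicate 2, lin-35 20 °C replicate 2, lin-35 26 °C replicate 2 and lin-37 26 °C replicate 1. The X share differed by 1.72 points for H3K9me2 and by -1.84 for H3K4me3 with equal peak numbers (26 °C minus 20 °C, exact permutation p = 0.00154 each, and 0.0139 when multiplied by 9 tests). Without lin-15B 20 °C replicate 2 the 61 H3K4me3 regions called at 26 °C only became 102. The 38 H3K9me2 regions became 59 without wild type 20 °C replicate 1 or lin-15B 20 °C replicate 1, 69 without lin-15B 26 °C replicate 1 and 62 without lin-15B 26 °C replicate 2. The 5 H3K9me2 regions called at 26 °C only became 8, 8 and 10 without wild type 20 °C replicate 1, 20 °C replicate 2 and 26 °C replicate 2, and 8 without lin-15B 26 °C replicate 2. They became 9, 12 and 14 without lin-35 20 °C replicate 2, 26 °C replicate 1 and 26 °C replicate 2, and 10 without lin-37 26 °C replicate 1. The 2 H3K4me3 regions called at 20 °C only became 8, 8 and 4 without wild type 20 °C replicate 1, 26 °C replicate 1 and 26 °C replicate 2. They became 5 and 9 without lin-15B 20 °C replicate 1 and 26 °C replicate 2, 6 without lin-35 20 °C replicate 2 and 4 without lin-37 20 °C replicate 2.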

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

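The tests of explanations in this part were chosen after their results were seen, except that equal peak numbers were planned for the odds ratios of H3K9me2 loss. Of 56 groups of 4 libraries tested for a single library far from the other 3, 2 had one, and chance alone gives about 1 in 20. H3K9me2 covered 11.7 Mb in lin-35 20 °C replicate 2, and the nearest of the other lin-35 libraries covered 8.97 Mb. At the sites that gained H3K4me3 in lin-15B, lin-37 20 °C replicate 1 had H3K9me2 at 64.7%, and the nearest of the other lin-37 libraries at 54.3%. H3K9me2 peak number differed from wild type in opposite directions at the 2 temperatures, and this difference between temperatures was not tested. For lin-35 the difference from wild type was 1539.5 peaks at 20 °C and -2115.5 at 26 °C, a change of -3655. For lin-37 it was 1744.5 and -1550, a change of -3294.5.

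Sums of lost and gained regions were compared with other splits of the same libraries. For H3K9me2 the splits argue against chance in lin-15B, lin-35 and lin-37. Only 1 of 35 splits, the real one, gave as many as 465, 224 and 164 regions, and the highest others gave 104, 55 and 67. A share of 1 in 35 is the smallest possible and was not adjusted for the number of comparisons, so chance is not excluded. The splits also do not separate genotype from library set. For H3K4me3 they argue against chance, with the same limits, in lin-15B and lin-35 (1 of 35 splits each, 262 and 193 regions, highest others 132 and 53). Within 20 °C alone, though, the split of the lin-15B and wild-type libraries by library set gave 486 regions and the real one 465. Within the set of 8 H3K4me3 libraries the real lin-15B sum was 958 and the highest other 308, and among the other libraries 635 and 214. For H3K4me3 in lin-37, 2 of 35 splits reached 107, the real one and the split by temperature (140), so the 35 splits do not argue against chance there. Of the 18 splits with 2 libraries of each temperature on each side, too few for a share under 0.05, the highest other gave 12. Of the 83 gains in lin-37, 69 were shared with lin-15B and 66 with lin-35. Independent lists would share 6.70 and 4.42, and simulated unchanged mutants shared at most 3 each. The overlap exceeds both, but unchanged mutants give short lists, so their overlap is no reference for lists of the real length. Independent lists take every region as equally likely to switch, which was not tested, so the overlap does not exclude chance. For regions called at 1 temperature only, 1 of 100 splits reached the real sums of 43 for H3K9me2 and 63 for H3K4me3, with 27 and 25 in the highest others.

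H3K4me3 appeared in a minority of the H3K9me2 regions lost in the mutants; weak wild-type peaks could give such losses, and in lin-35, the only mutant with fewer H3K9me2 peaks than wild type on average (8732 against 9020), so could shorter lists. Matching on covered length and score rank argues against weak peaks as the whole cause, since 17.2%, 11.5% and 10.9% of the regions lost in lin-15B, lin-35 and lin-37 had H3K4me3 switched on and the matched draws reached 5.02%, 4.17% and 3.40% at the upper end of their 95% range. With equal peak numbers the odds ratio of H3K9me2 loss at sites that gained H3K4me3 was 12.3 in lin-35 (Fisher's exact p = 7.1e-11), which argues against list length there. In the 3 of 4 libraries each of lin-15B and lin-35 that shared a library set with wild type, H3K9me2 at the gained sites lay below the single wild-type library by more than the wild-type SD and the difference between temperatures (smallest differences -23.6 and -26.5 points), which argues against library set as the whole cause in these libraries. In the remaining library of each and in lin-37, with 0 libraries in such a set, set and genotype cannot be told apart, and a change of chromatin state in the mutants stays a hypothesis, found and tested in the same libraries.

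The higher X share of H3K9me2 in lin-15B may reflect more called peaks, more X DNA in the extracts or the library set. With equal peak numbers 3 of 4 lin-15B libraries still lay above every wild-type library (8.23% ± 3.03 against 4.20% ± 0.505, n = 4), which argues against peak number. X DNA could raise the H3K4me3 X share as well, and that share differed by -1.35 percentage points (exact permutation p = 0.286), in the other direction. Peaks were called against an input library, which could offset such DNA, and the inputs were not analysed. This comparison therefore cannot decide on X DNA. The exception, lin-15B 20 °C replicate 1, had the looser q cutoff of 0.05, and it was the only lin-15B library with a wild-type library of its set at the same temperature (difference 1.14 points, wild-type SD 0.631). The other 2 comparisons within sets (4.82 and 10.1 points) were across temperatures, between which lin-15B itself differed by 4.98 points. The 10.1 points exceeded that difference plus the wild-type SD (5.62). The 4.82 points set lin-15B at 20 °C against wild type at 26 °C. Both had higher X shares at 26 °C, so temperature would narrow this difference. Library set stays open, since each set held 1 wild-type library and 1 lin-15B library shared no set with wild type.

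A segment of the left arm of V, V 2350471 to 2543484 (ce10, 193 kb), held 7 H3K9me2 regions lost in all 3 mutants, and the next longest run elsewhere held 3. H3K9me2 covered 54.1 ± 6.40 kb of it in wild type and 13.3 ± 4.65, 20.8 ± 1.97 and 21.7 ± 7.27 kb in lin-15B, lin-35 and lin-37 (n = 4), in a segment chosen for this difference. Shorter lists on average apply to lin-35 alone, where all 7 stayed lost with equal peak numbers, which argues against them there. The wild-type peak pattern repeated at a spacing of 108.2 kb (r = 0.909 across 100 bp bins, which are not independent, against at most 0.613 in 100 other windows), so a duplicated segment whose copy number differs between the strains is a candidate explanation. Without read depth this cannot be told apart from a loss of the mark; without the segment the lost regions numbered 270, 181 and 140.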

How the results depend on the processing

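Of 934 recomputed values for 67 results, 795 kept their direction and their side of the threshold, or stayed within 1.5 times for counts. Another 76 values could not change and are left out. They come from a −log10 q of at least 2, which removed 0 H3K4me3 peaks (38), an overlap of 200 bp for H3K4me3, whose shortest peak was 250 bp (14), a replicate block on counts of switched regions, which it does not enter (12), and odds ratios of wild-type H3K9me2 without a mutant H3K9me2 library (12). Chosen after seeing the data were the 1 kb bins, the 200 bp overlap except for the odds ratios of H3K9me2 loss, the 3 of 4 rule for those odds ratios, and every alternative for zone odds ratios, odds ratios of wild-type H3K9me2, regions shared by mutants, X shares, site shares and temperature counts; the other settings were planned. The planned promoter windows, operon genes and gene list results were not run, and a q filter cannot be applied to H3K9me2, whose score is not known to be q. Without read counts, a region missed for lack of depth cannot be told from a region without the mark. Where no reason is given, the cause was not tested.

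Asking for at least 3 of 4 against at most 1 of 4 libraries, a looser rule by construction, gave more regions. H3K9me2 lost and gained regions numbered 873 and 1313 in lin-15B, 630 and 295 in lin-35, and 539 and 294 in lin-37. H3K4me3 lost and gained regions numbered 96 and 629, 261 and 338, and 188 and 251. Shared H3K9me2 losses were 363 (lin-15B and lin-35), 443 (lin-15B and lin-37) and 314 (lin-35 and lin-37), and shared H3K4me3 gains 216, 161 and 136.

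In 1 kb bins H3K9me2 was lost in 127 and gained in 51 bins in lin-35, and 97 and 28 in lin-37; H3K4me3 was lost in 0, 13 and 10 bins in lin-15B, lin-35 and lin-37. Shared H3K9me2 losses were 61, 71 and 49 bins, and H3K4me3 was called at 20 °C only in 4 and at 26 °C only in 40. With an overlap of 200 bp 97 H3K9me2 regions were lost in lin-37. With a −log10 q of at least 5, H3K4me3 was lost in 2, 15 and 15 regions and called at 20 °C only in 1. The H3K4me3 peak number of lin-35 then differed from wild type by 13 peaks, where all peaks gave -30.5 (exact permutation p = 1), and the H3K4me3 arm share of lin-37 by 1.48 points (exact permutation p = 0.0571). With arms of 25% that arm share differed by 1.33 points (exact permutation p = 0.0857), and the H3K9me2 arm share by 0.0216 points in lin-35 and 0.0539 in lin-37, where arms of 30% gave -0.0979 and -0.0281.

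With equal peak numbers lin-15B gained H3K9me2 in 76 regions and lost H3K4me3 in 25, lin-37 gained H3K9me2 in 28, H3K9me2 was called at 26 °C only in 10 and H3K4me3 at 20 °C only in 15. The arm odds ratio of H3K4me3 gains in lin-35 was 1.26 (Fisher's exact p = 0.155). Unadjusted permutation p over genotypes was 0.0480 for the H3K9me2 arm share and 0.0296 for the H3K4me3 arm share. The H3K4me3 arm share differed by 2.81 points in lin-15B (exact permutation p = 0.0286) and by 1.19 between temperatures (0.0494), and the H3K9me2 X share by 1.72 between temperatures (0.00154).

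Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated between -0.0399 and 0.0428 for H3K9me2 (0 of 6 pairs above 0.1) and between -0.144 and 0.110 for H3K4me3 (1 of 6). With a replicate block the H3K4me3 arm share gave a permutation p of 0.0311 over genotypes and a temperature difference of 1.06 points (exact permutation p = 0.00781). The differences of -42.3, -32.6 and -45.2 points in H3K9me2 at gained sites had p = 0.125, the smallest exact p that 4 pairs allow. The block left 10 other test results on their side of the threshold.

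Leaving out 1 library loosens the rule for a switched region by construction. H3K9me2 losses ranged from 283 to 471 in lin-15B and 152 to 283 in lin-37, and gains from 198 to 679, 35 to 61 and 18 to 62 in lin-15B, lin-35 and lin-37. H3K4me3 losses ranged from 4 to 34, 24 to 64 and 25 to 54, and gains in lin-15B from 258 to 426. Shared H3K9me2 losses ranged from 95 to 172, 113 to 215 and 82 to 154. H3K9me2 regions called at 20 °C only ranged from 39 to 69 and at 26 °C only from 6 to 14, and H3K4me3 regions from 2 to 9 and 62 to 102.

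For the per-library values, the permutation p over genotypes ranged from 0.0351 to 0.765 for H3K9me2 peak number and from 0.0354 to 0.179 for the H3K4me3 arm share. The H3K9me2 peak number differed from wild type by -954 to 149 in lin-35 and -413 to 544 in lin-37, and between temperatures by -1267 to -431. The H3K9me2 arm share differed by -0.477 to 0.349 points in lin-35, -0.407 to 0.419 in lin-37 and -0.619 to 0.0853 between temperatures, and the X share by 4.00 to 6.97 in lin-15B, 1.38 to 1.88 in lin-35 and 0.587 to 2.07 between temperatures. The H3K4me3 peak number differed by -381 to 358 in lin-35 and -174 to 489 in lin-37, and its arm share by 1.98 to 3.25 points in lin-15B, 1.1 to 1.72 in lin-37 and 0.726 to 1.43 between temperatures (exact permutation p = 0.0370 without lin-35 26 °C replicate 2). The exact p of the temperature difference in H3K9me2 peak number was 0.0355 without lin-15B 20 °C replicate 1.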

Other observations

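In this part the predictions for lin-15B sites without H3K4me3 in another mutant were written before their values were seen; the test of the difference between classes of sites and the regions named were chosen after. The mutants differed in which sites gained H3K4me3, and H3K9me2 followed the site and the mutant. At 83 sites that gained H3K4me3 in lin-15B and had none in any lin-35 library, H3K9me2 was called at 82.8% ± 9.04 in wild type and 79.2% ± 1.52 in lin-35 (n = 4), against 44.9% ± 6.48 in lin-15B. At the 107 sites that gained H3K4me3 in both, it was called at 82.0% ± 8.68 in wild type and 45.8% ± 4.89 in lin-35. For lin-37 the 69 sites without H3K4me3 had 82.6% ± 6.80 in wild type and 74.3% ± 5.47 in lin-37, and the 69 sites gained in both 88.4% ± 7.67 and 38.8% ± 7.43. An example is IV 13292787 to 13293797, which lost H3K9me2 and gained H3K4me3 in all 4 lin-15B libraries, and had H3K9me2 in 4 of 4 and H3K4me3 in 0 of 4 libraries of both lin-35 and lin-37.

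The hypothesis that H3K9me2 falls only where H3K4me3 appears in the same mutant was tested at these sites. For lin-35 the difference from wild type was -3.61 percentage points (exact permutation p = 0.457), with 0 of 4 libraries below the wild-type range, which is consistent with the hypothesis. For lin-37 it was -8.33 points (exact permutation p = 0.171), with 2 of 4 libraries below the range, so a smaller fall without H3K4me3 stays open there. The difference from wild type at the sites gained in both, minus that at the sites without H3K4me3, was -32.6 points in lin-35 and -41.3 points in lin-37 (exact permutation p = 0.0286 each, the smallest possible). Outside these sites the hypothesis does not hold as stated. H3K4me3 was switched on in the same mutant at 17.2% of the H3K9me2 regions lost in lin-15B, 11.5% in lin-35 and 10.9% in lin-37. These shares ask for no wild-type library and all 4 mutant libraries, so partial gains are left out. All 4 mutant libraries had H3K4me3, gained or not, at 55.2%, 50% and 50.3% of these lost regions. Even in any library, with wild type and the other mutants counted, it was called at only 73.5%, 60.9% and 64.6% of them. The 7 regions of the segment on V, where copy number may differ, are among those without it. Peak calls are all or none, so a partial fall of H3K9me2 could be missed. The order of the changes cannot be read from these libraries.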
